A study of Mus musculus with 27 samples.

How the data were processed

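Gene expression was measured by poly(A) RNA sequencing in 27 libraries of E14Tg2a mouse embryonic stem cells, 9 groups of 3 biological replicates from 3 independent time courses. Per the labels' protocols, libraries followed the TruSeq stranded mRNA procedure and were sequenced in paired-end mode on a NovaSeq instrument. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie and edgeR and the genome build mm10, with no versions given. The annotation release, the strand setting and the filters used by the authors are not given in the sources used here.

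The authors deposited 7 tables, 1 for each treated time against its untreated group, each with 38352 genes. Per the file headers, the values used here are FPKM for each library as made by the authors, with no further scaling between libraries stated. The deposited fold is the ratio of the mean FPKM of the 3 treated libraries to that of the 3 untreated ones, as the values show, and the deposited log2 column is the log2 of that ratio. The deposited p-value and q-value columns and the significance mark come from the authors' own test, taken to be edgeR as named in the submitters' processing notes, with settings and criteria not given in the sources used here. Only the FPKM values entered the tests here; the authors' mark was counted for comparison. The untreated 0 h columns recur in several tables, and 0 of the duplicate columns differed. A gene symbol was shared by 153 genes, so genes were joined by Ensembl identifier.

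FPKM hides the number of reads, so absolute depth is unknown. Relative depth was read from genes below 0.05 FPKM, where values rise in steps of single fragments, as the most frequent ratio to untreated 0 h replicate 1. Gene positions, lengths and GC content came from GENCODE M21 on GRCm38, with GC content and length for 13602 of the 13614 tested genes.

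For the tests, FPKM was converted to log2(FPKM + 1) and genes at 1 FPKM or more in at least 3 libraries were kept, which left 13614. A single limma model with a mean-variance trend was fitted to all 27 libraries with 1 mean per group, so every comparison shares the spread estimated over 9 groups. Contrasts were each treated time from 0.5 h to 10 h minus untreated 0 h, treated 24 h minus untreated 24 h, untreated 24 h minus untreated 0 h, the 24 h effect minus the 10 h effect, and each treated time minus the one before it. The p-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes with an adjusted p below 0.05 were called changed. They set each difference against the spread between replicates, as estimated over all 9 groups. The median SE of a change was 0.13, and 0.184 for the difference of the 24 h and 10 h effects. At an unadjusted p below 0.05 the counts were 1352, 1033, 4739, 6668, 6568, 5770 and 4307 at 0.5 h to 24 h, 1285 between the untreated groups and 2830 for the difference of effects.

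The groups, comparisons, tests and 32 gene lists were fixed before the data were examined. Lists with at least 5 tested members were tested with camera from limma at a preset correlation between genes of 0.01, in 8 comparisons, and the 256 p-values were adjusted together. The same lists were tested with an estimated correlation and with fry. Members past the limma test were counted over all genes and with p-values adjusted over the list alone. For the difference between the 24 h and 10 h effects and for the steps between times the lists were tested in the same way.

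Genes are named by a rule fixed at the same time. In each comparison it takes the 5 largest rises and the 5 largest falls among changed genes that have a mean of at least 5 FPKM in the higher group and every treated library on the same side of every control library, gene models without a usual symbol left out. It adds up to 4 members of each described list with the largest change among changed members, or up to 2 highly expressed ones where none changed, and a panel of 27 genes at every time. Of the panel, Slc7a11 was not among the tested genes. The text names only part of the genes that the rule takes. The rule leaves out some genes of the 0.5 h comparison (Trim52, Nlrp12, Snhg1 and Smad7) and mt-Tl1 at that time; they were chosen after their values were seen. Genes listed under enriched terms in the closing section were also chosen after their values were seen.

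Alternatives planned before were a pseudocount of 0.1, no filter or a filter of 5 FPKM, median-of-ratios scaling, no mean-variance trend, both untreated groups as control, only the libraries of the groups compared, a replicate block alone and with scaling, a minimum change of 2-fold (1 on the log2 scale), and each library left out in turn. Added after the data were seen were library weights, a correction of each library for GC content and length (natural splines with 4 degrees of freedom each), and fits that leave out libraries standing apart. Of these, 4 libraries were taken as standing apart because their mean correlation with the other 2 of their group lay at least 0.01 below the correlation of those 2. That rule was set after these 4 had been noticed from their GC trends, and its first form was changed because it took whole groups; the largest gap among the other libraries is 0.00429. A second such fit also leaves out untreated 24 h replicates 1 and 3, so that the untreated 24 h group then holds 1 library.

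The limma test was tested on simulated data shaped like the 4 h comparison, with 50 genes at each change: 64%, 92%, 98% and 100% of changes of 1.5-fold, 2-fold, 3-fold and 4-fold were recovered, with 7 unchanged genes called. The changed genes were drawn from genes above 5 FPKM in untreated 0 h cells. Camera called a simulated list of 20 genes shifted by 0.3 and did not call a random list. The simulated genes varied independently of each other, without shifts of whole libraries. This simulation therefore cannot tell how often camera calls lists whose genes are correlated. Other splits of the libraries were counted for each comparison, all 10 where 3 libraries are set against 3, and 100 drawn with seed 11 for the difference of effects.

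Gene Ontology terms of 10 to 500 genes were tested for enrichment among genes changed at least 2-fold (27810 tests, adjusted together), a test chosen after the data were seen. Some enriched terms are described in the closing section, and the others are not reported here. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. Reads were not used here.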

Results

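Polyadenylated RNA from mouse embryonic stem cells was sequenced to ask whether a brief oxidant exposure alters gene expression, and how any change develops over a day. The cells were E14Tg2a, a mouse embryonic stem cell line, grown on gelatin with serum, leukemia inhibitory factor (LIF) and the inhibitor pair known as 2i, a medium that holds cells in the naive pluripotent state. Hydrogen peroxide (H2O2), a reactive oxygen species that crosses membranes, was applied for 30 min at 500 µM according to the treatment protocol. The series description gives the same figure in mM, so the unit rests on the protocol. The medium was then replaced with spent medium from untreated cells. The 27 libraries form 9 groups of 3 biological replicates: untreated cells at 0 h and at 24 h, and treated cells at 0.5 h, at even hours from 2 h to 10 h, and at 24 h. Cells of the 0.5 h group were collected directly after the exposure. Treated cells at 0.5 h to 10 h were compared with untreated cells at 0 h, and treated cells at 24 h with untreated cells at 24 h, so time in culture is matched only at 24 h. No group is labeled as given the change of medium alone. From 2 h on, effects of peroxide and of that change cannot be told apart.

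Expression was given as FPKM (fragments per kilobase of transcript, scaled to all mapped fragments of a library), so absolute sequencing depth is unknown. Steps between low FPKM values placed the depth of the other libraries at 0.981 to 1.10 times that of untreated 0 h replicate 1, and between 11516 and 12607 genes reached 1 FPKM in each library. Changes are differences of mean log2(FPKM + 1), a scale that understates the change of weakly expressed genes, and the value in brackets after a change is its standard error (SE). Among the genes followed through time, on GRCm38 (mm10) with GENCODE M21 annotation, Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984 and Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273. Mdm2 (ENSMUSG00000020184) spans 117688875 to 117710758 on chromosome 10, and Cdkn1a (ENSMUSG00000023067) spans 29090976 to 29100727 on chromosome 17. Hmox1 (ENSMUSG00000005413) occupies 75093621 to 75100589 of chromosome 8, and Srxn1 (ENSMUSG00000032802) 152105516 to 152111376 of chromosome 2. Nanog (ENSMUSG00000012396) is annotated at 122707489 to 122714633 on chromosome 6. Sox2 (ENSMUSG00000074637) and Txnip (ENSMUSG00000038393) are both on chromosome 3, at 34650405 to 34652461 and at 96557957 to 96561883.

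Some libraries stood apart from the others of their group. Set against the mean of untreated 0 h replicates 1 and 2, expression in untreated 0 h replicate 3 increased by 0.41 on the log2 scale per 10 points of transcript GC content, and ribosomal protein mRNAs lay 0.90 higher. Its summed FPKM was 395760. Treated 2 h replicate 1 showed the same features (0.37 per 10 points, 0.80 and 378400), and treated 8 h replicate 3 and 10 h replicate 3 showed them less strongly (0.22 per 10 points in both). The whole 4 h group carried the trend too, with GC slopes of 0.232, 0.145 and 0.195 in replicates 1, 2 and 3 and ribosomal protein shifts of 0.438, 0.281 and 0.354, so no 4 h replicate stood apart from the other 2. The remaining libraries summed to between 294480 and 347780 FPKM, the highest being untreated 24 h replicate 3. Untreated 24 h replicates 1 and 3 had GC slopes of 0.20 and 0.12 and ribosomal protein shifts of 0.38 and 0.44. In 6 h replicates 1, 2 and 3 the GC slopes were 0.117, 0.129 and 0.123. Ribosomal protein shifts in these 6 h libraries were 0.270, 0.216 and 0.245. Transcripts of hepatocytes, a cell type the cultures should lack, were also uneven. The summed FPKM of 31 hepatocyte genes was 69.0 to 97.0 in the 0.5 h libraries, 64.8 to 86.3 in untreated 24 h cells, 69.6 in 6 h replicate 3, and 87.5 and 79.2 in 8 h replicates 1 and 2, against 11.4 in untreated 0 h replicate 3 and 2.17 to 3.50 elsewhere. The astrocyte genes Gfap and Lcn2 stood at 1.73 to 2.90 and 2.00 to 3.65 FPKM in all 0.5 h, 8 h and untreated 24 h libraries. In untreated 0 h cells they reached at most 0.246 and 0.0206, and at 2 h, 6 h, 10 h and treated 24 h they were uneven between replicates.

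**Figure D1:**
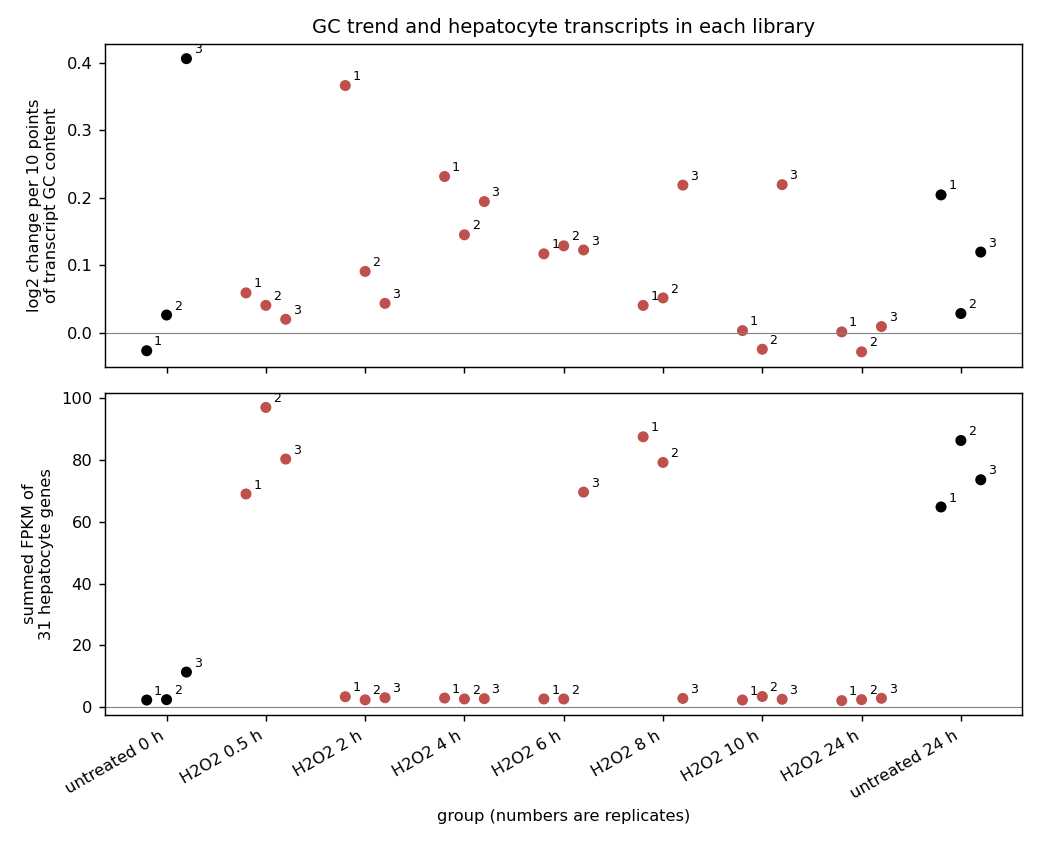
GC trend and hepatocyte transcripts in each of the 27 libraries (black, untreated; red, treated; the digit beside each point is the replicate). The upper panel gives the log2 change in expression per 10 points of transcript GC content, which reached 0.41 in untreated 0 h replicate 3 and 0.37 in 2 h replicate 1, and the lower panel gives the summed FPKM of 31 hepatocyte genes, which was either 64.8 or above or 11.4 or below.

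Directly after the exposure, mRNAs of the oxidant, DNA damage and growth signal responses did not pass the test. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, stood at 89.9 ± 5.77 FPKM (SD, n = 3) against 89.0 ± 1.68 in untreated cells. Fos, an immediate early transcription factor, stood at 1.02 ± 0.10 against 0.935 ± 0.317, and Mdm2, the p53 ubiquitin ligase, at 38.0 against 34.8. The clearest falls were in mitochondrial transfer RNAs: mt-Ta fell from 25.3 ± 13.4 to 3.44 ± 0.479 FPKM (log2 change −2.46, SE 0.21, adjusted p = 1.71e-06), mt-Tw changed by −2.89 (0.28), mt-Tn by −2.22 (0.21), mt-Tc by −1.94 (0.19) and mt-Tt by −1.82 (0.34). These genes are short and abut the mitochondrial mRNAs on a shared precursor, so reads of one can be counted to the other. Of 13614 genes tested, 11 changed in limma at an adjusted p below 0.05, with 2 higher and 9 lower. The 2 higher genes were Rsrp1, of an arginine- and serine-rich protein (39.7 ± 2.64 against 27.9 ± 3.97 FPKM, adjusted p = 0.0414), and Trim52, which lay below 1 FPKM. Nlrp12, Snhg1 and Smad7, an inhibitor of TGF-beta signaling, were among the lower ones (Smad7 log2 change −0.44, SE 0.07).

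Gene lists moved at 0.5 h without any member passing the test over all genes. Ribosomal protein mRNAs had a median change of −0.36 (0 of 87 members changed, 0 when adjusted over the list alone; camera adjusted p = 3.02e-23, adjusted p = 0.365 with an estimated correlation). Their most abundant member, Rplp1, stood at 1330 against 2070 FPKM (log2 change −0.54, SE 0.24, adjusted p = 0.476). The same test called nuclear respiratory chain genes lower (median −0.25, 0 of 31, adjusted p = 6.18e-08, adjusted p = 0.365 with an estimated correlation) and mitochondrially encoded mRNAs lower (median −0.22, 0 of 13, 2 lower when adjusted over the list alone, adjusted p = 0.000526, adjusted p = 0.483 with an estimated correlation). Histone and DNA methylation enzymes were called higher (median 0.31, 0 of 28, adjusted p = 0.000359, adjusted p = 0.705 with an estimated correlation), as were homologous recombination and checkpoint genes (median 0.19, 0 of 20, adjusted p = 0.0154, adjusted p = 0.742 with an estimated correlation). Replication-dependent histones (median −0.20, 0 of 32, adjusted p = 0.00261) and antioxidant enzymes outside the NRF2 list (median −0.10, 0 of 28, adjusted p = 0.00788) were called lower, with adjusted p = 0.544 and 0.577 with an estimated correlation. For these last 4 lists none of the members passed when adjusted over the list alone, nor did any nuclear respiratory chain gene. With the 4 libraries that stood apart left out, the ribosomal protein median was −0.07 (adjusted p = 4.86e-05), the other 6 medians lay between −0.03 and 0.02 with no call, and 47 genes changed, 30 higher and 17 lower. The count was 7 without untreated 0 h replicate 3 or without 0.5 h replicate 1, and 6 without 0.5 h replicate 2. When only the 6 compared libraries were fitted, 15 genes changed, all higher, and 0 of the 11 genes above, the mitochondrial tRNAs included, were among them.

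At 2 h the immediate early genes rose and the first pluripotency genes fell. Egr1 increased from 0.161 ± 0.107 to 9.84 ± 2.66 FPKM (log2 change 3.20, SE 0.13, adjusted p = 6.51e-13) and Fos from 0.935 ± 0.317 to 11.5 ± 0.401 (2.71, SE 0.13, adjusted p = 5.08e-12). Both encode transcription factors induced within minutes by growth and stress signals. Jun, the partner of Fos, rose by 1.47 (0.09), and the stress factor Atf3 by 1.46 (0.10). Sox2, a core pluripotency factor, fell from 132 ± 9.56 to 78.9 ± 2.03 FPKM (−0.73, SE 0.06, adjusted p = 3.22e-08). Foxd3 changed by −1.05 (0.13), and Fgf4, a growth factor secreted by pluripotent cells, by −0.83 (0.08). Txnip, the inhibitor of thioredoxin, went from 60.0 ± 10.7 to 30.1 ± 3.48 FPKM (−0.96, SE 0.10). The heat shock chaperone genes Hspa1a and Hspa1b rose by 1.09 (0.20) and 0.94 (0.17), while Dnajb1 did not pass (0.01). Neither did Nanog (303 ± 26.8 against 344 ± 42.0 FPKM, −0.18, SE 0.08), Hmox1 (0.07), Mdm2 (−0.06) or Cdkn1a (−0.08).

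By list, 12 of 28 immediate early genes were higher and 4 lower at 2 h (17 and 5 when adjusted over the list alone), with a median of 0.31 (camera adjusted p = 5.56e-17). Core pluripotency genes had 4 of 14 lower and 0 higher, Sox2, Foxd3, Sall4 and Tdgf1, with the same count adjusted over the list alone (median −0.13, adjusted p = 1.03e-08). Among naive pluripotency genes 2 of 18 were lower, Fgf4 and Gbx2, and 3 when adjusted over the list alone (median −0.16, adjusted p = 1.31e-05). These 3 lists kept their calls with an estimated correlation. Mitochondrially encoded mRNAs were called lower with 1 of 13 changed, mt-Nd3, a subunit of complex I (218 against 506 FPKM), and 3 when adjusted over the list alone (median −0.16, adjusted p = 1.81e-05, adjusted p = 0.351 with an estimated correlation). After a GC and length correction the call was lost (adjusted p = 0.0545). Mitochondrial tRNAs again had the largest falls, with mt-Tl1 at 50.6 ± 3.52 against 220 ± 25.2 FPKM (−2.09, SE 0.15) and mt-Tt, mt-Tw, mt-Ta and mt-Tn at −2.09, −1.88, −1.65 and −1.47. Endoplasmic reticulum (ER) stress chaperones had 1 of 19 lower, Xbp1 (−0.35, SE 0.08), also when adjusted over the list alone (adjusted p = 0.000748, adjusted p = 0.106 with an estimated correlation).

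In all, 145 genes changed at 2 h, 68 higher and 77 lower, and 23 of them by at least 2-fold. Tested directly against 0.5 h, Egr1 was higher by 3.01 (adjusted p = 1.13e-12), Fos by 2.63 and Jun by 1.47, Sox2 was lower (−0.57), and 159 genes differed between these times. The 2 h group and its control each hold a library with a strong GC trend. With the 4 libraries that stood apart left out 342 genes changed (88 higher and 254 lower), and 308 (91 and 217) without untreated 0 h replicate 3 alone. The count was 252 after the GC and length correction, 1655 with library weights, 301 against both untreated groups, and 3 when only the 6 compared libraries were fitted.

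**Figure D2:**
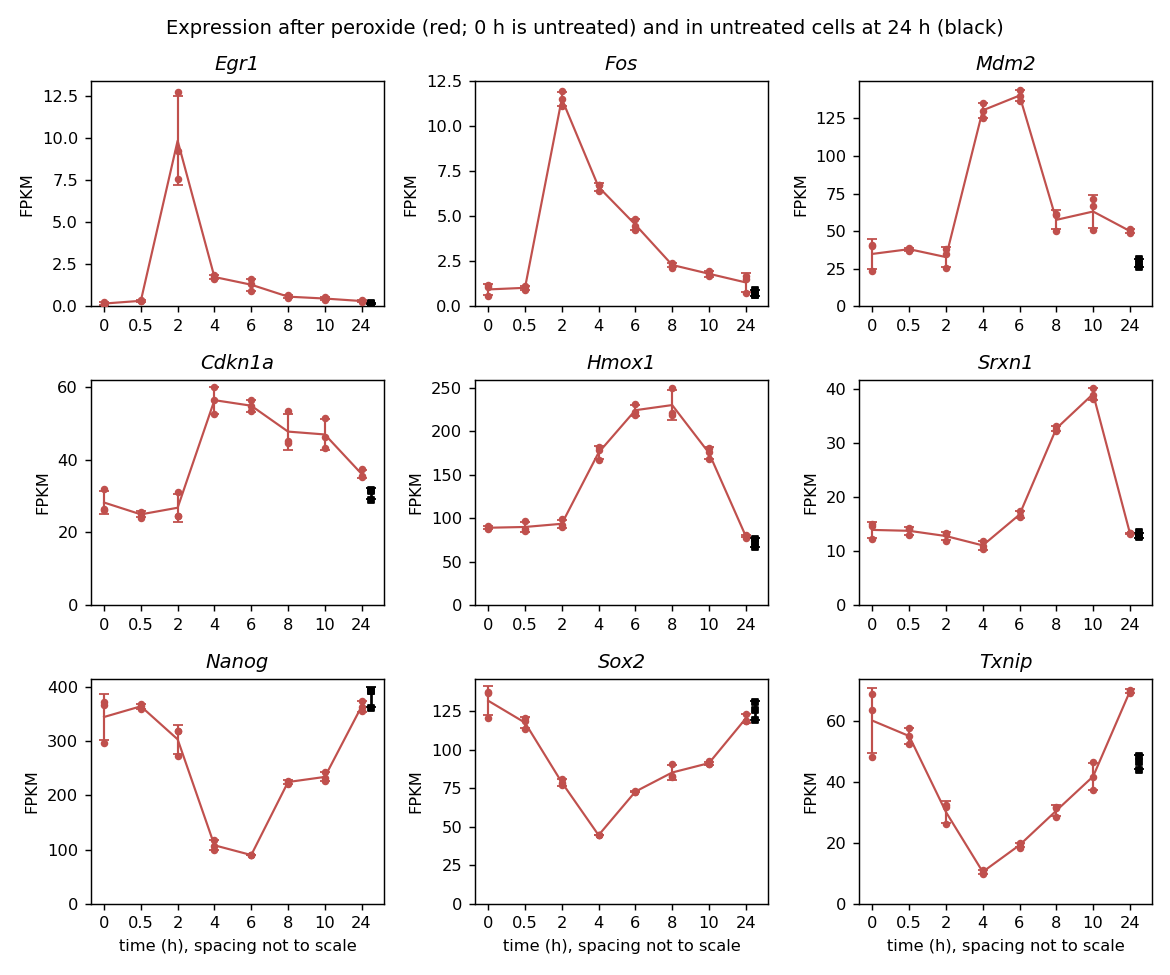
FPKM of 9 genes against time after H2O2 was added (red points, treated replicates, with untreated 0 h cells at time 0; red line and bars, mean and SD, n = 3; black squares, untreated cells at 24 h; time spacing not to scale). Egr1 reaches 9.84 and Fos 11.5 at 2 h, Mdm2 130 at 4 h and 140 at 6 h, Hmox1 230 at 8 h and Srxn1 39.1 at 10 h, while Nanog is at 89.8 at 6 h, Sox2 at 44.6 and Txnip at 10.5 at 4 h.

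At 4 h targets of p53, the transcription factor activated by DNA damage, rose together, and pluripotency mRNAs fell further. Mdm2 increased from 34.8 ± 9.96 to 130 ± 5.01 FPKM (log2 change 1.92, SE 0.17, adjusted p = 1.27e-08) and Cdkn1a, the inhibitor of cyclin-dependent kinases p21, from 28.2 ± 3.21 to 56.4 ± 3.75 (0.98, SE 0.09). Hmox1 rose from 89.0 ± 1.68 to 176 ± 7.78 FPKM (0.97, SE 0.07, adjusted p = 3.42e-10). Nanog fell from 344 ± 42.0 to 108 ± 9.13 (−1.66, SE 0.08, adjusted p = 1.79e-12) and Sox2 to 44.6 ± 0.196 (−1.54, SE 0.06). Pou5f1, which encodes Oct4, did not pass the test at 705 ± 28.4 against 713 ± 195 FPKM (0.02, SE 0.15, adjusted p = 0.961), and neither did Esrrb (0.10) or Klf4 (−0.18).

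Of 33 p53 targets, 24 were higher and 1 lower (26 and 1 when adjusted over the list alone), with a median of 0.82 (adjusted p = 3.80e-14). They included Plk2 (1.89, SE 0.14), the translesion polymerase gene Polk (1.65, SE 0.21) and the mTOR inhibitor gene Ddit4 (1.56, SE 0.07). Core pluripotency genes had 9 of 14 lower and 0 higher, the same adjusted over the list alone (median −0.68, adjusted p = 3.53e-10), with Foxd3 falling from 18.1 ± 3.43 to 1.5 ± 0.0589 FPKM (−2.92, SE 0.13) and Sall4 changing by −1.45. Naive genes had 9 of 18 lower and 1 higher, the same adjusted over the list alone (median −0.36, adjusted p = 1.33e-06), led by Fgf4 (−1.90), Nr5a2 (−1.79) and Klf2 (−1.38); their median was −0.68 with the 4 libraries that stood apart left out. Formative and primed genes fell in 6 of 11 cases, the same adjusted over the list alone (median −0.48, adjusted p = 0.000236), among them Tcf15, Zic2 and Zic5. Trophectoderm genes had 3 of 7 lower, the same adjusted over the list alone (median −0.27, adjusted p = 0.00453, and 0.0516 without the 4 libraries that stood apart and untreated 24 h replicates 1 and 3), with Eomes at −1.15 and Tfap2c at −0.70. The p53, core, naive, formative and trophectoderm calls held with an estimated correlation.

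Mitotic genes were lower at 4 h for 13 of 30 G2/M members and higher for 1 (17 and 1 when adjusted over the list alone; median −0.30, adjusted p = 1.32e-05, adjusted p = 0.190 with an estimated correlation). The mitotic kinase genes Aurka (28.0 against 58.0 FPKM, −1.02, SE 0.05) and Plk1 (−0.91, SE 0.07) led them. Immediate early genes split, with 13 of 28 higher and 9 lower (14 and 9 adjusted over the list alone; median 0.25, adjusted p = 0.0280, adjusted p = 0.264 with an estimated correlation and 0.154 after the GC and length correction). Fosl1, an AP-1 factor, rose from 0.100 ± 0.0426 to 5.49 ± 0.874 FPKM (2.55, SE 0.12) and Maff, a small Maf factor, by 2.53 (0.12), while Ccn2, a matricellular growth factor gene, changed by −1.94 (0.12). Primitive streak genes had 6 of 11 lower and 1 higher (6 and 2 adjusted over the list alone; median −0.26, adjusted p = 0.0299, adjusted p = 0.246 with an estimated correlation). Neuroectoderm genes had 4 of 5 lower and 1 higher, the same adjusted over the list alone (median −0.58, adjusted p = 0.0356, adjusted p = 0.123 with an estimated correlation). Both calls were lost with the 4 libraries left out (adjusted p = 0.265 and 0.122). NRF2 targets, the genes of the main antioxidant transcription factor, were not called (4 of 25 higher, 1 lower, adjusted p = 0.153). Srxn1, the sulfiredoxin gene on that list, was lower (11 ± 0.783 against 13.9 ± 1.51 FPKM, −0.31, SE 0.07), a call lost after the GC and length correction.

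Other large changes at 4 h were falls of Mycn, a Myc family factor (30.5 ± 3.65 to 4.50 ± 0.211 FPKM, −2.51, SE 0.08, adjusted p = 3.90e-15), Txnip (to 10.5 ± 0.583, −2.40, SE 0.10) and the kinase gene Sgk1 (−2.10, SE 0.12). Large rises were those of mt-Tq (2.78, SE 0.35), Snora34 (2.75) and Sp6 (2.60, SE 0.49). Commd5 changed by −2.34 with an SD as large as its mean (3.70 ± 4.16 FPKM). The glutathione-degrading enzyme gene Chac1 fell by 1.26. In total 3577 genes changed, 1936 higher and 1641 lower, 341 by at least 2-fold. Lower genes were the majority after scaling (1786 higher and 2014 lower), without untreated 0 h replicate 3 (1904 and 2504) and with the 4 libraries left out (3111 and 3772). Against 2 h, Mdm2 was higher by 1.98 (adjusted p = 1.24e-08), Hmox1 by 0.90 and Cdkn1a by 1.05, Egr1 (−1.96) and Nanog (−1.48) were lower, and 2732 genes differed. The count was 6883 with the 4 libraries left out, 7776 with library weights, 2291 among genes at 5 FPKM or more and 1061 when only the 6 compared libraries were fitted.

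At 6 h the p53 response and the loss of pluripotency mRNAs were both broad. Mdm2 stood at 140 ± 3.63 FPKM (log2 change 2.02, SE 0.17, adjusted p = 2.38e-09), the death receptor gene Fas rose from 0.293 to 4.28 (2.03, SE 0.11), and the apoptosome gene Apaf1 from 5.44 to 23.8 (2.02, SE 0.24). Nanog fell to 89.8 ± 0.106 FPKM (−1.92, SE 0.08, adjusted p = 8.84e-14) and Tdgf1, the Nodal co-receptor gene, from 195 to 83.5 (−1.21, SE 0.05). Hmox1 reached 224 ± 6.16 FPKM (1.32, SE 0.07, adjusted p = 1.18e-12). The largest rise was of Klhl26, a kelch-like family gene, from 6.21 ± 0.840 to 74.3 ± 0.714 FPKM (3.39, SE 0.08, adjusted p = 2.62e-17). It was followed by mt-Tq (3.31), Fosl1 (3.05), the cell adhesion gene Nectin4 (1.06 ± 0.173 to 14 ± 0.549 FPKM, 2.87, SE 0.09) and mt-Tm (2.67).

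Of the p53 targets 26 of 33 were higher and 1 lower (27 and 1 adjusted over the list alone; median 0.76, adjusted p = 5.29e-11). Core pluripotency genes were lower for 12 of 14, the same adjusted over the list alone (median −0.84, adjusted p = 4.66e-10), with Foxd3 at −2.36 and Utf1 at −1.41. Naive genes were lower for 9 of 18 and higher for 2, the same adjusted over the list alone (median −0.49, adjusted p = 0.000526), with Prdm14 at −1.89 (11.2 to 2.24 FPKM) and Nr5a2 at −1.49. Formative genes had 8 of 11 lower and 1 higher, the same adjusted over the list alone (median −0.52, adjusted p = 0.000684), with Tcf15 at −1.92. All 4 calls held with an estimated correlation. Pou5f1 (−0.26, SE 0.15, adjusted p = 0.175), Klf4 (−0.06) and Esrrb (0.17) did not pass.

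G2/M genes had 16 of 30 lower and 1 higher at 6 h, the same adjusted over the list alone (median −0.40, adjusted p = 1.82e-05, adjusted p = 0.194 with an estimated correlation). Plk1 went from 72.7 to 26 FPKM (−1.45, SE 0.07), Cdk1 from 49.4 to 25.3 (−0.93) and Cdc20 from 174 to 91.2 (−0.92). Immediate early genes had 16 of 28 higher and 5 lower (16 and 6 adjusted over the list alone; median 0.39, adjusted p = 0.000456, adjusted p = 0.0716 with an estimated correlation). Trophectoderm genes had 4 of 7 lower, 5 adjusted over the list alone (median −0.48, adjusted p = 0.0106, adjusted p = 0.0553 with an estimated correlation), with Eomes at −1.46. Neuroectoderm genes had 4 of 5 lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.0444, adjusted p = 0.142 with an estimated correlation, 0.0844 with the 4 libraries left out), with the tubulin gene Tubb3 at −1.54. Among further falls were the Ras family gene Eras (21 ± 5.63 to 3.98 ± 0.535 FPKM, −2.12, SE 0.18), Cdc42ep5 (−2.36), Zfp428 (−1.95) and Chac1 (−1.67). Asparagine synthetase, Asns, fell from 229 ± 13.7 to 169 ± 3.30 FPKM (−0.43, SE 0.06).

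At 6 h 5761 genes changed, 3032 higher and 2729 lower, 772 by at least 2-fold. Here too lower genes were the majority without untreated 0 h replicate 3 (2624 higher and 3068 lower), with the 4 libraries left out (3461 and 4177) and after the GC and length correction (3256 and 3354). Compared with 4 h, Sox2 was higher by 0.70 (adjusted p = 3.60e-08), Txnip by 0.82, Srxn1 by 0.56 and Hmox1 by 0.35, and Nanog lower (−0.26, adjusted p = 0.0254), among 2739 genes that differed. Hepatocyte transcripts were present in 6 h replicate 3 and low in the other 6 h libraries (69.6 against 2.71 and 2.70 FPKM). The count was 3620 among genes at 5 FPKM or more and 2713 when only the 6 compared libraries were fitted.

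**Figure D3:**
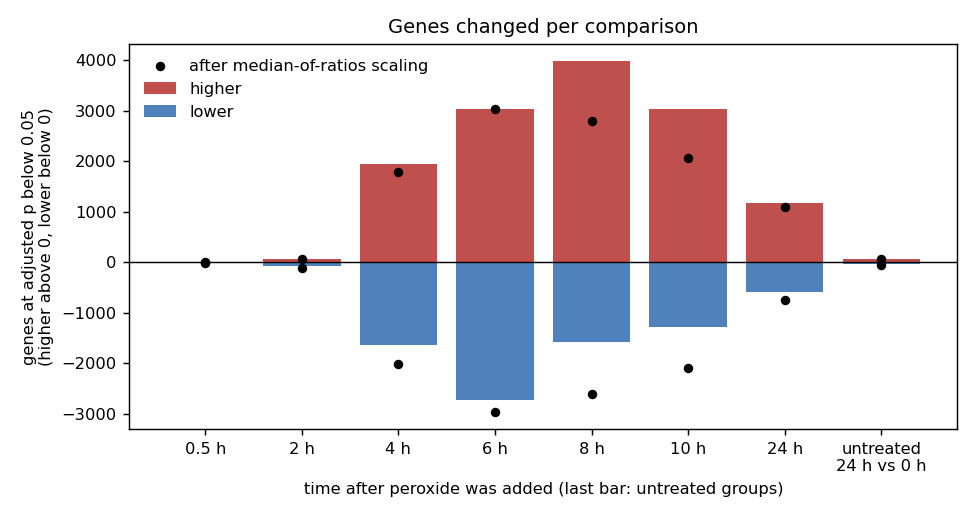
Genes with an adjusted p below 0.05 in each comparison (red, higher; blue, lower; n = 3 per group), with black points after median-of-ratios scaling. Higher and lower counts are 3032 and 2729 at 6 h, 3969 and 1576 at 8 h (2797 and 2603 scaled) and 58 and 38 between the untreated groups.

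By 8 h the antioxidant genes Srxn1 and Gclm had joined Hmox1, while p53 targets were less raised than at 6 h. Srxn1 rose from 13.9 ± 1.51 to 32.7 ± 0.438 FPKM (log2 change 1.18, SE 0.07, adjusted p = 5.43e-11), Gclm, of glutathione synthesis, by 0.65 (0.07), and Hmox1 stood at 230 ± 17.3 (1.36, SE 0.07). Plaur, the urokinase receptor gene, increased from 4.01 ± 0.371 to 22.3 ± 2.51 FPKM (2.22, SE 0.11, adjusted p = 4.32e-12) and Klhl26 stood at 31.6 ± 1.22 (2.18). Mdm2 was at 57.5 ± 6.40 FPKM (0.74, SE 0.17, adjusted p = 0.00114). Nanog (224 ± 3.18 FPKM, −0.61, SE 0.08), Sox2 (85.3 ± 4.63, −0.62, SE 0.06) and Pou5f1 (532 ± 69.5, −0.40, SE 0.15, adjusted p = 0.0419) were lower than in untreated cells; the Pou5f1 call was lost without the expression filter. Against 6 h, Mdm2 was lower (−1.28, adjusted p = 5.66e-06), and Nanog (1.31, adjusted p = 4.60e-10), Srxn1 (0.92) and Gclm (0.61) were higher. As lists, p53 targets were lower than at 6 h (median −0.40, adjusted p = 5.11e-11) and core pluripotency genes higher (0.30, adjusted p = 0.0036, adjusted p = 0.0907 with an estimated correlation).

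The median gene lay 0.146 higher at 8 h and 0.127 higher at 10 h than after median-of-ratios scaling, so list medians at these times are followed by their scaled value. At 8 h core pluripotency genes were lower for 11 of 14, 12 adjusted over the list alone (median −0.61, scaled −0.79, adjusted p = 2.78e-10). Targets of ATF4, the factor of the amino acid and integrated stress response, were lower for 13 of 25 and higher for 3 (14 and 3 adjusted over the list alone; −0.32, scaled −0.49, adjusted p = 3.69e-06), with the amino acid transporter gene Slc7a3 at −1.22 (0.08), Pck2 at −0.97 and Cebpg at 0.84. Immediate early genes were higher for 19 of 28 and lower for 2 (22 and 2 adjusted over the list alone; 0.49, scaled 0.38, adjusted p = 1.38e-05). The p53 targets were higher for 21 of 33, the same adjusted over the list alone (0.39, scaled 0.25, adjusted p = 8.44e-05), with Pmaip1, of the BH3 protein Noxa, at 1.36 and Perp at 1.34. Formative genes had 5 of 11 lower and 1 higher, also adjusted over the list alone (−0.34, scaled −0.51, adjusted p = 0.00369). These 5 calls held with an estimated correlation. ER chaperones were lower for 9 of 19 and higher for 2 (9 and 3 adjusted over the list alone; adjusted p = 0.00418, adjusted p = 0.168 with an estimated correlation), with Hspa5, of BiP, at 74.7 against 135 FPKM (−0.84, SE 0.11). Ribosome biogenesis genes had 8 of 20 lower, the same adjusted over the list alone (−0.24, scaled −0.40, adjusted p = 0.000372, adjusted p = 0.194 with an estimated correlation), with the nucleolar protein genes Nop58 and Nop56 at −0.53 and −0.44. Falls among single genes were led by Notum, a secreted Wnt-inactivating enzyme (14.5 ± 2.86 to 4.41 ± 0.478 FPKM, −1.51, SE 0.14), Crxos (−1.40), Fgf17 (−1.39), mt-Tw (−1.37) and Hnrnpa3 (−1.37), the last with a wide spread (12.6 ± 7.07 FPKM).

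At 8 h 5545 genes changed, 3969 higher (71.6%) and 1576 lower, 312 by at least 2-fold; after scaling 2797 were higher (51.8%) and 2603 lower. Hepatocyte transcripts were high in 8 h replicates 1 and 2 and low in replicate 3. The count was 3396 among genes at 5 FPKM or more and 1537 when only the 6 compared libraries were fitted.

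At 10 h primitive streak genes and Wnt targets were higher, and pluripotency, ATF4 target and ER chaperone mRNAs lower. Several NRF2 targets rose as well. Srxn1 reached 39.1 ± 1.05 against 13.9 ± 1.51 FPKM (log2 change 1.43, SE 0.07, adjusted p = 9.51e-12), and Cbr3, a carbonyl reductase gene, rose by 1.38 (0.12), the autophagy receptor gene Sqstm1 by 1.27 (0.09) and the quinone reductase gene Nqo1 by 0.52 (0.06). Lefty1 and Lefty2, Nodal antagonists, rose from 4.48 to 14.9 FPKM (1.55, SE 0.16) and from 7.74 to 20.4 (1.29, SE 0.10). The Wnt target Sp5 rose from 1.82 to 7.95 (1.67, SE 0.13), and T, of the mesoderm factor Brachyury, from 0.266 to 2.38 (1.42, SE 0.08). Both Lefty genes were also higher in untreated cells at 24 h than at 0 h. Pou5f1 was lower at 448 ± 60.3 against 713 ± 195 FPKM (−0.64, SE 0.15, adjusted p = 0.00268), with Klf4 at −0.54 and Zfp42 at −0.34; the Klf4 call was lost after the GC and length correction. Compared with 8 h, Hmox1 was lower (−0.39, adjusted p = 0.000934), and Srxn1 (0.25, adjusted p = 0.0348), Nqo1 (0.37) and Lefty1 (1.08) were higher.

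NRF2 targets had 13 of 25 higher and 2 lower (13 and 3 adjusted over the list alone; median 0.36, scaled 0.21, adjusted p = 0.00654, adjusted p = 0.240 with an estimated correlation). Primitive streak genes had 9 of 11 higher and 0 lower, also adjusted over the list alone (0.61, scaled 0.50, adjusted p = 0.000149). Wnt targets had 5 of 7 higher and 1 lower, Notum (6 and 1 adjusted over the list alone; 0.90, scaled 0.77, adjusted p = 0.00418). Immediate early genes were higher for 22 of 28 and lower for 1, the same adjusted over the list alone (0.54, scaled 0.47, adjusted p = 6.34e-09), led by Arc, Jun, Dusp1 and Rhob at 1.21, 1.16, 1.15 and 1.08. The p53 targets were higher for 18 of 33, 21 adjusted over the list alone (0.31, scaled 0.23, adjusted p = 0.000125). Core genes were lower for 11 of 14, the same adjusted over the list alone (−0.52, scaled −0.67, adjusted p = 3.70e-10), naive genes for 5 of 18, 8 adjusted over the list alone (−0.25, scaled −0.40, adjusted p = 0.000104). ATF4 targets were lower for 14 of 25 and higher for 3 (15 and 3 adjusted over the list alone; −0.38, scaled −0.52, adjusted p = 1.60e-08), including the serine synthesis gene Phgdh (41.0 to 19.4 FPKM, −1.04, SE 0.10) and Slc7a3 (−1.26). ER chaperones were lower for 11 of 19 and higher for 2 (13 and 2 adjusted over the list alone; −0.39, scaled −0.54, adjusted p = 1.69e-06), with Manf at −0.89, Hsp90b1 at −0.78 and Calr at −0.69. All of these calls except that of the NRF2 targets held with an estimated correlation. Glycolysis genes were lower for 8 of 16 and higher for 2 (9 and 2 adjusted over the list alone; −0.27, scaled −0.42, adjusted p = 8.44e-05, adjusted p = 0.0698 with an estimated correlation), with the lactate dehydrogenase gene Ldha at −0.81. The G2/M list was called lower (5 of 30 lower, 4 adjusted over the list alone, adjusted p = 0.0311, adjusted p = 0.571 with an estimated correlation). Before scaling its median was 0.01 and its mean −0.05, while the median over all tested genes was 0.109.

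Plaur (2.07, SE 0.11) and the mitochondrial tRNAs mt-Tq, mt-Tm, mt-Tp and mt-Ty (3.46, 2.86, 2.37 and 2.02) had the largest rises at 10 h. The largest falls were of Tuba3a (52.3 ± 8.54 to 18.5 ± 1.40 FPKM, −1.44), Crxos (−1.41), the autophagy receptor gene Calcoco2 (153 ± 15.4 to 57.7 ± 1.34, −1.39, SE 0.07), Myl9 (−1.38) and mt-Tw (−1.36). Changes passed the test for 4309 genes, 3025 higher (70.2%) and 1284 lower, 167 by at least 2-fold; after scaling 2056 were higher (49.6%) and 2092 lower. The count was 2611 among genes at 5 FPKM or more and 484 when only the 6 compared libraries were fitted.

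A day after the exposure, treated cells were compared with untreated cells of the same time. The pluripotency factors and early oxidant genes did not pass the test. Nanog stood at 364 ± 9.94 against 381 ± 18.4 FPKM (log2 change −0.07, SE 0.08) and Sox2 at 120 ± 2.71 against 126 ± 6.13 (−0.06, SE 0.06). Hmox1 stood at 79.4 ± 1.46 against 72.2 ± 4.84 (0.14, SE 0.07, adjusted p = 0.154) and Srxn1 at 13.3 ± 0.0609 against 12.9 ± 0.454 (0.04). A set of p53 targets was higher: Perp, a desmosomal and apoptosis gene, at 42.2 ± 2.31 against 16.3 ± 1.33 FPKM (1.32, SE 0.06, adjusted p = 1.54e-11), and Mdm2 at 50.1 ± 1.21 against 28.7 ± 2.79 (0.79, SE 0.17, adjusted p = 0.00355). Trp53inp1, Pmaip1 and Plk2 were higher by 1.08, 1.08 and 1.03. Cdkn1a did not pass (0.23, SE 0.09, adjusted p = 0.113). Genes of glycolysis were lower, among them Tpi1 (62.5 against 129 FPKM, −1.04, SE 0.14), Ldha (232 against 386, −0.73, SE 0.06) and the lactate exporter gene Slc16a3 (1.92 ± 0.264 against 7.03 ± 1.05, −1.46, SE 0.13). Peg10, an imprinted retrotransposon-derived gene, was the largest rise (41.0 ± 3.16 against 10.0 ± 1.55 FPKM, 1.93, SE 0.17), followed by S100a6 (1.68, SE 0.20), Perp, mt-Tp (1.30) and the hyaluronidase gene Hyal1 (1.18).

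The largest falls at 24 h were of liver genes present in untreated 24 h cells. Alb, serum albumin, stood at 0.0486 ± 0.0305 in treated against 20.2 ± 4.49 FPKM in untreated cells (−4.32, SE 0.94, adjusted p = 0.00451) and Apoa2 at 0.0944 against 11.1 (−3.46, SE 0.75), while Fabp1 was listed at 0 in all treated libraries against 5.59 in untreated ones. Rpl17 was also lower (97.3 ± 42.2 against 326 ± 48.8 FPKM, −1.80, SE 0.41). The p53 list had 17 of 33 higher and 0 lower, 20 adjusted over the list alone (median 0.32, adjusted p = 8.87e-08). Glycolysis had 9 of 16 lower and 1 higher, 10 and 1 adjusted over the list alone (−0.26, adjusted p = 1.73e-06). Both calls held with an estimated correlation, and the glycolysis median was −0.16 after the GC and length correction. Ribosomal protein mRNAs were called lower with 8 of 87 lower, 5 adjusted over the list alone (−0.42, adjusted p = 1.21e-17, adjusted p = 0.481 with an estimated correlation). Their median was −0.24 without the 4 libraries that stood apart and untreated 24 h replicates 1 and 3, the pair with the raised GC slope, which leaves a single untreated 24 h library, replicate 2, as control. Nuclear respiratory chain genes had 7 of 31 lower, 11 adjusted over the list alone (−0.33, adjusted p = 3.35e-08, adjusted p = 0.351 with an estimated correlation; −0.16 against that single control library). ATF4 targets had 6 of 25 lower and 1 higher (11 and 2 adjusted over the list alone; −0.18, adjusted p = 0.000246, adjusted p = 0.0717 with an estimated correlation), with Atf4 itself at −0.50.

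Genes of the 2-cell-like state, a rare totipotent-like state of these cultures, were higher for 4 of 13, 9 adjusted over the list alone (median 0.52, adjusted p = 0.00259, adjusted p = 0.544 with an estimated correlation). They were Usp17le (1.05), Tdpoz3 (1.01), Zscan4d (31.9 against 20.5 FPKM, 0.61, SE 0.20) and Arg2 (0.59). Several of these belong to families of near-identical copies, so reads can be split among them. Primitive endoderm genes had 5 of 9 higher and 1 lower (6 and 1 adjusted over the list alone; median 0.51, mean 0.20, adjusted p = 0.00394, adjusted p = 0.303 with an estimated correlation), with Dab2 at 0.70 and Sparc at 0.54, and with Ttr, also a liver gene, at −2.24. Immediate early genes were higher for 9 of 28 and lower for 1, also adjusted over the list alone (0.15, adjusted p = 0.00267, adjusted p = 0.131 with an estimated correlation), a call lost with the 4 libraries left out (adjusted p = 0.0577); Ccn1 (0.85) and Btg2 (0.78) led. HIF targets, genes of the hypoxia response, were lower for 4 of 18 and higher for 1 (6 and 2 adjusted over the list alone; −0.10, adjusted p = 0.0444, adjusted p = 0.433 with an estimated correlation), a call lost after the GC and length correction (adjusted p = 0.108). Their largest fall was of Bnip3, a mitophagy gene (7.18 against 14.7 FPKM, −0.94, SE 0.12). Nqo1 (0.65, SE 0.06) and Txnip (69.6 ± 0.600 against 46.3 ± 2.29 FPKM, 0.58, SE 0.10) were higher. Set against untreated 0 h cells, treated 24 h cells differed by −0.05 for Ccn1 (SE 0.09, adjusted p = 0.703), −0.01 for Bnip3 (SE 0.12, adjusted p = 0.972) and 0.22 for Nqo1 (SE 0.06, adjusted p = 0.0235).

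At 24 h 1757 genes changed, 1175 higher and 582 lower, 71 by at least 2-fold. The count was 1040, 968 and 1017 without treated replicates 1, 2 and 3, and 959 and 881 without untreated 24 h replicates 1 and 3. It was 6987 with the 4 libraries that stood apart left out, 7465 with library weights, 4882 when only the 6 compared libraries were fitted, and 1091 among genes at 5 FPKM or more. None of those 4 is in the groups compared, so leaving them out changed only the estimate of the spread. With untreated 24 h replicates 1 and 3 left out beside those 4 it was 2416, from 1 control library that is assumed to vary like the other groups.

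Untreated cells themselves differed between 24 h and 0 h, the only measure of what time in culture does. Lefty1 rose from 4.48 ± 1.2 to 12.6 ± 1.65 FPKM (log2 change 1.33, SE 0.16, adjusted p = 0.000118) and Lefty2 from 7.74 ± 0.251 to 20.9 ± 2.45 (1.32, SE 0.10, adjusted p = 3.31e-07). Genes of glycolysis and of the hypoxia response were higher, including Slc16a3 (2.74 ± 0.498 to 7.03 ± 1.05 FPKM, 1.10, SE 0.13), Bnip3 (7.18 ± 0.236 to 14.7 ± 2.37, 0.93, SE 0.12), Pgk1 (0.53), Ldha (0.49), Tpi1 (0.65) and the glucose transporter gene Slc2a1 (0.27). Ccn1 fell from 11.6 ± 0.407 to 5.74 ± 0.274 FPKM (−0.90, SE 0.09), Nqo1 from 48.3 to 35.7 (−0.43, SE 0.06) and Hmox1 from 89.0 to 72.2 (−0.30, SE 0.07, adjusted p = 0.0329, a call lost after scaling). Trh, the thyrotropin-releasing hormone gene, rose by 0.84, and Fgfbp1, the ribosomal RNA gene mt-Rnr2, Nefm and Snhg1 changed by −0.79, −0.69, −0.57 and −0.50.

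Glycolysis genes were higher for 7 of 16, 10 adjusted over the list alone (median 0.28, adjusted p = 6.54e-13), and HIF targets for 4 of 18, 11 adjusted over the list alone (0.26, adjusted p = 9.04e-12). ATF4 targets were higher for 1 of 25, Ddit4, and for 4 adjusted over the list alone (0.13, adjusted p = 2.02e-05). These 3 calls held with an estimated correlation. Cholesterol synthesis genes were called higher with 0 of 21 changed, 2 adjusted over the list alone (0.21, adjusted p = 0.000114, adjusted p = 0.200 with an estimated correlation), a call lost with the 4 libraries left out (adjusted p = 0.0997). NRF2 targets had 2 of 25 lower, 3 adjusted over the list alone (−0.04, adjusted p = 0.000774, adjusted p = 0.145 with an estimated correlation, 0.298 with the 4 libraries left out). In this comparison 96 genes changed, 58 higher (60.4%) and 38 lower, 13 by at least 2-fold; after scaling 55 were higher (46.6%) and 63 lower. Hepatocyte transcripts were high in the 24 h group and low in the 0 h group. The count was 61 and 208 without untreated 0 h replicates 2 and 3, 45, 44 and 33 without untreated 24 h replicates 1, 2 and 3. It was 4100 (1593 higher and 2507 lower) with the 4 libraries left out, 247 with those and untreated 24 h replicates 1 and 3 left out (1 library against 2), 259 after the GC and length correction, 5021 with library weights and 12 when only the 6 libraries were fitted.

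The effect at 24 h was then tested against the effect at 10 h, each relative to its own untreated group. Srxn1 (−1.39, SE 0.10, adjusted p = 8.01e-09), Hmox1 (−0.83, SE 0.09), Lefty1 (−2.64, SE 0.22) and Jun (−0.82, SE 0.12) had a lower effect at 24 h than at 10 h. Nanog (0.48, SE 0.11), Sox2 (0.46, SE 0.08), Klf4 (0.68, SE 0.15) and Txnip (1.08, SE 0.15) differed in the upward direction. Mdm2 did not pass (−0.08, SE 0.23, adjusted p = 0.913), nor did Perp (0.08, SE 0.09) or Nqo1 (0.13, SE 0.09). The core pluripotency list moved up between the effects (median 0.45, adjusted p = 6.13e-10), as did ER chaperones (0.32, adjusted p = 1.27e-06), ATF4 targets (0.29, adjusted p = 8.26e-05) and formative genes (0.31, adjusted p = 0.00267). Immediate early (−0.38, adjusted p = 5.69e-06), primitive streak (−0.55, adjusted p = 5.55e-06) and Wnt target genes (−0.83, adjusted p = 0.00049) moved down. All 7 of these calls held with an estimated correlation. The p53 (−0.02, adjusted p = 0.927) and glycolysis lists (0.00, adjusted p = 0.775) were not called. The effects differed for 1184 genes, 401 upward (33.9%) and 783 downward, 95 by at least 2-fold, and after scaling for 641 upward (53.1%) and 567 downward. The count was 2260 without untreated 0 h replicate 3, 3665 with the 4 libraries left out and 417 when only the 12 libraries involved were fitted.

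**Figure D4:**
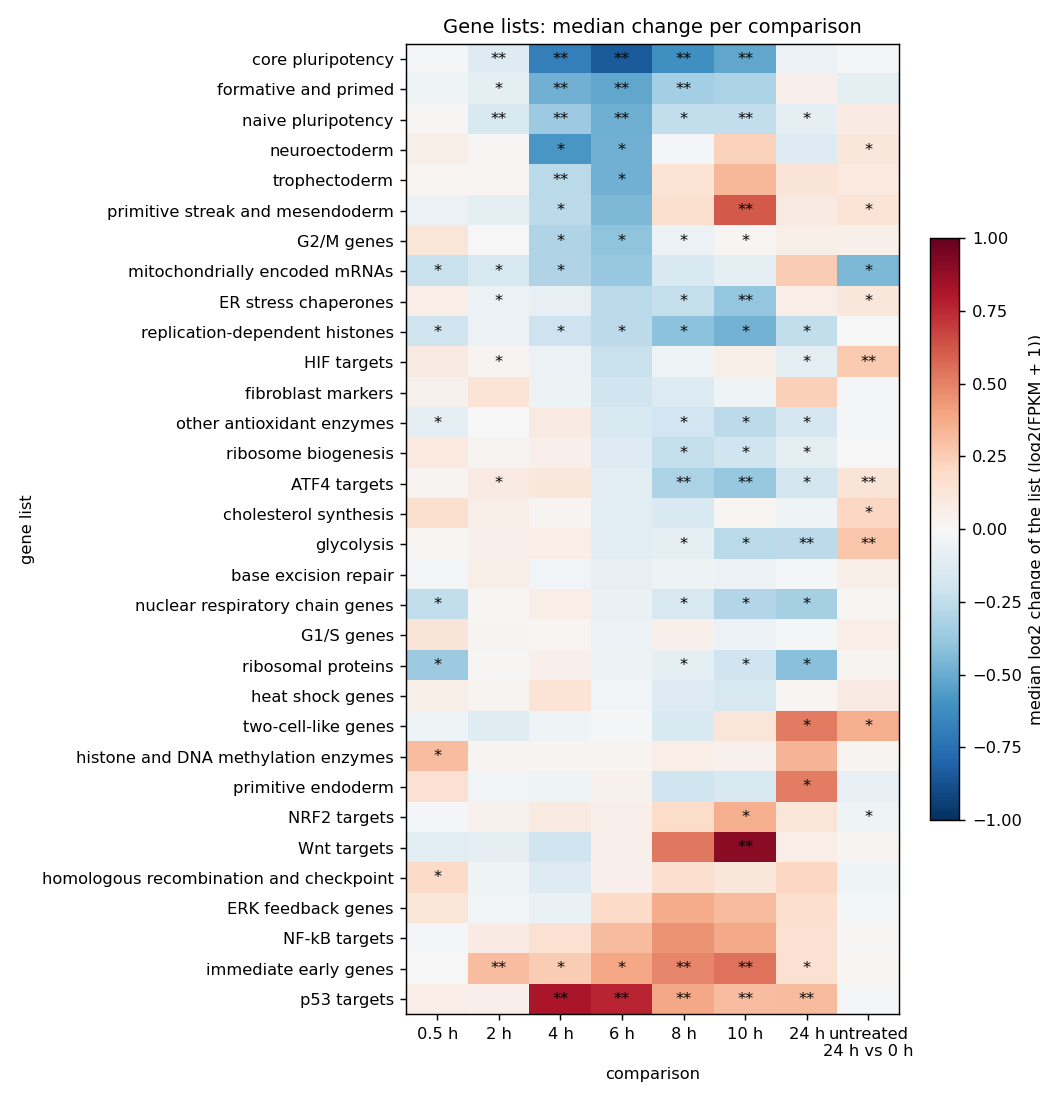
Median log2 change of each of 32 gene lists (vertical) in each of 8 comparisons (horizontal), red higher and blue lower (log2(FPKM + 1), n = 3 per group); * marks a camera adjusted p below 0.05, and ** one that also holds with an estimated correlation. The p53 list is at 0.82 at 4 h and 0.32 at 24 h, and the core pluripotency list at −0.84 at 6 h and −0.52 at 10 h.

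Of the 32 lists, 6 were called in no comparison. Their lowest adjusted p values were 0.0672 for fibroblast markers (5 tested genes, median 0.14 at 2 h), 0.0723 for heat shock genes (0.03 at 2 h) and 0.0724 for NF-kB targets (0.45 at 8 h). They were 0.105 for G1/S genes (0.13 at 0.5 h), 0.153 for ERK feedback genes (−0.01 between the untreated groups) and 0.196 for base excision repair (−0.02 at 24 h).

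In the authors' deposited table, 159, 88, 1253, 2523, 1416, 934 and 872 genes carry the authors' significance mark, in order of time from 0.5 h to 24 h. Of these marked genes in the authors' deposited table, 31, 29, 794, 1497, 831, 524 and 371 were among the 13614 tested here, and 5, 21, 781, 1488, 824, 509 and 256 also passed the limma test. The criterion behind the mark is not given in the sources used here.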

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

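Of the tests below, the 2 tests of liver transcripts, the test of astrocyte transcripts, the 3 tests of ribosomal protein mRNAs and the comparison of treated 24 h with untreated 0 h cells were chosen after the result was seen; the GC-corrected test of glycolysis genes and the splits of the libraries were chosen before.

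Effects at 2 times differed from each other. The effect of the treatment at 24 h was measured against untreated 24 h cells, and that at 10 h against untreated 0 h cells. These effects differed for 1184 genes. Antioxidant genes were among them, with differences of −0.83 for Hmox1 (SE 0.09, adjusted p = 5.60e-06), −1.39 for Srxn1 (SE 0.10, adjusted p = 8.01e-09) and −0.83 for Gclm (SE 0.11, adjusted p = 2.64e-05). The p53 target Cdkn1a differed by −0.49 (SE 0.13, adjusted p = 0.0243) and the immediate early gene Jun by −0.82 (SE 0.12, adjusted p = 0.000158). Upward differences were 0.51 for Asns (SE 0.08, adjusted p = 0.000223), 0.46 for Sox2 (SE 0.08, adjusted p = 0.000553), 0.48 for Nanog (SE 0.11, adjusted p = 0.00887), 0.68 for Klf4 (SE 0.15, adjusted p = 0.00622) and 1.08 for Txnip (SE 0.15, adjusted p = 5.15e-05). The 2 effects have different controls, so a drift of untreated cells within the first 10 h, which was not measured, enters the difference.

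Other splits of the same libraries were fitted to ask how often a grouping without meaning calls as many genes. For the difference of effects, 11 of 100 splits gave at least the real 1184 genes, the real one among them. The highest other split gave 6482. In each of the others the treated libraries of 1 of the 2 times stayed together, so a whole effect of the treatment remained in it. Such splits are not free of meaning and cannot tell whether chance could give this count. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. Real counts and highest others were 11 and 0 at 0.5 h, 3577 and 0 at 4 h, 5761 and 0 at 6 h, 5545 and 0 at 8 h, 4309 and 795 at 10 h, and 1757 and 0 at 24 h, with 1 split as large, the real one, in each. At 2 h 5 splits were as large (145 and 6760) and between the untreated groups 2 (96 and 5579). In these 2 comparisons some splits gave several times the real count. They place untreated 0 h replicate 3 together with 2 h replicate 1, or with untreated 24 h replicates 1 and 3. This points to a structure shared by these libraries.

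Liver transcripts were present in whole groups and in single libraries of other groups. A response of the cells to peroxide or to time is argued against by the replicates: in 2 groups, 6 h and 8 h, the summed FPKM of the hepatocyte genes differed over 10 times between replicates, by 25.8 and 30.4 times. RNA or reads from liver as the source was tested on hepatocyte genes not looked at before. Of these, 61.5% (8 of 13) were at least 5 times higher in 6 h replicate 3 than in both others. This lies between the 80% set for this source and the 50% set against it. The 8 genes that passed reached at most 0.0472 FPKM in replicates 1 and 2. Those that fell short had higher levels there: Ahsg 0.764 and 0.71, Hpx 0.441 and 0.243, Cps1 0.204 and 0.295. F2 had 0.258 and 0.353, and Serpinc1 0.0967 and 0.0531. All of these but F2 were higher in replicate 3 than in both others. Such levels limit the fold that added RNA can give, so the test cannot decide and this source stays open. For astrocyte transcripts the like test, between treated 24 h replicates 1 and 3, gave 0 (0 of 9 genes). However, 5 of the 9 genes were too high in replicate 3 for a gain as large as that of Gfap to raise them 5 times. Of the rest, Fabp7 (0.542 against 0.16 FPKM) and S100b (0.56 against 0.306) were higher in replicate 1. Slc1a2 (0.194 against 0.19) was about equal and Acsbg1 (0.192 against 0.229) lower. Gfap (2.16 against 0.149) and Aqp4 (0.290 against 0.0419), looked at before, were higher in replicate 1. RNA or reads from astrocytes stays open. A first form of both tests had counted genes already looked at and gave 68.8% and 10%.

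Ribosomal protein mRNAs were called lower at 0.5 h and at 24 h at camera's preset correlation, with 0 and 8 of 87 members lower (adjusted p = 0.365 and 0.481 with an estimated correlation). At 0.5 h the median went from −0.36 to −0.07 with the 4 libraries that stand apart left out, so most of it could come from those libraries; the preset correlation still gave a call (adjusted p = 4.86e-05). The GC and length correction took the median to −0.30 at 0.5 h (camera adjusted p = 2.14e-16) and from −0.42 to −0.37 at 24 h (adjusted p = 3.76e-12). This argues against the trend with GC content and length that was removed as the whole cause at both times. A bias of single libraries that the correction does not remove stays open. A response to peroxide stays open at 24 h, as does a difference between the untreated 24 h libraries.

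Glycolysis and HIF target mRNAs were called lower at 24 h than in untreated cells of that time, the HIF targets with adjusted p = 0.433 with an estimated correlation and 0.108 after the GC and length correction. Against untreated 0 h cells, the 2 lists together had a median of 0.09 in treated 24 h cells (SD 0.02 over 3 libraries, 33 genes). Much of the difference may thus be a rise between 0 h and 24 h that untreated cells showed and treated cells lacked or showed less. This does not cover Ldha, which lay below untreated 0 h cells (−0.24, SE 0.06, limma adjusted p = 0.0079). The 2 lists were not tested apart. By the list medians above, HIF targets had risen by more in untreated cells than they lay lower in treated ones. By library the medians were 0.227, 0.332 and 0.210 in untreated and 0.067, 0.068 and 0.099 in treated 24 h cells. The trend with GC content and length that the correction removes is argued against as the whole cause for the glycolysis genes, not for the HIF targets. With the correction the glycolysis median was −0.16 instead of −0.26 (camera adjusted p = 0.001). Whether the peroxide itself, a lower cell density after it, or the change of medium prevented the rise was not tested.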

How the results depend on the processing

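Library weights, the GC and length correction and the fits without 4 or 6 libraries were tests chosen after the data were seen; the other alternatives were planned. Counts below are in the order of the treated times from 0.5 h to 24 h, then untreated 24 h against 0 h, then difference of effects, where the main counts are 11, 145, 3577, 5761, 5545, 4309, 1757, 96 and 1184. All 9 counts stayed within 1.5 times under median-of-ratios scaling, a pseudocount of 0.1, no mean-variance trend, and the replicate block with or without scaling.

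With changes of at least 2-fold only, counts were 5, 23, 341, 772, 312, 167, 71, 13 and 95, by construction fewer. A filter of 5 FPKM tests fewer genes and gave 2291 at 4 h, 3620 at 6 h, 3396 at 8 h, 2611 at 10 h, 1091 at 24 h and 722 for the difference of effects. Without a filter 31 genes changed at 0.5 h, and with both untreated groups as control 26 at 0.5 h and 301 at 2 h. Fitting only the groups compared leaves fewer libraries to estimate the spread and gave 3, 1061, 2713, 1537, 484, 4882, 12 and 417 from 2 h on. Of these only the 24 h count lay above the main one. The groups were not equally even. Mean correlations with the group were 0.967, 0.969 and 0.942 for untreated 0 h replicates 1, 2 and 3. They were 0.988 to 0.994 in the 2 groups compared at 24 h. The spread shared over 9 groups may thus be too small for comparisons with untreated 0 h cells. At 24 h it may be too large. The main p-values from 0.5 h to 10 h may then be too low. At 0.5 h this setting gave 15, of which 0 were among the 11.

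Without the 4 libraries standing apart the counts were 47 at 0.5 h, 342 at 2 h, 6883 at 4 h, 6987 at 24 h, 4100 between the untreated groups and 3665 for the difference. Without 6 libraries they were 42, 703, 7479, 247 and 2499 at 0.5 h, 2 h, 4 h, between the untreated groups and for the difference; the last 2 rest on 1 untreated 24 h library, assumed to vary like the other groups. The GC and length correction gave 18 at 0.5 h, 252 at 2 h and 259 between the untreated groups. Library weights gave 204, 1655, 7776, 7465, 5021 and 4388 at 0.5 h, 2 h, 4 h, 24 h, between the untreated groups and for the difference. None of the 4 libraries standing apart is in the 24 h comparison, so leaving them out changed only the estimate of the spread there. All 1757 genes called with all libraries stayed called. For the other counts of these 4 settings the cause was not tested.

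Leaving out 1 library at a time gave 6 to 15, 101 to 308, 2927 to 4408, 4937 to 6016, 4385 to 5927, 3096 to 5054, 881 to 1686, 33 to 208 and 876 to 2260 genes. All values at 24 h lie below the 1757 of all libraries.

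The replicate numbers were not taken to pair the libraries, since no label ties a number to a shared day and correlations of same-numbered libraries ran from −0.80 to 0.80 (9, 19 and 7 of 36 pairs over 0.1 for numbers 1, 2 and 3). As a hint from the data, 15 of 27 libraries had their highest mean correlation with the libraries of their own number in other groups. With the replicate block the counts were 11, 142, 3710, 5927, 5763, 4540, 2043, 94 and 1217; 1 list call was gained and 1 lost, and of the named genes 2 calls were gained and 3 lost.

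Of 256 list tests, the estimated correlation ended 58 calls and added none, and fry ended 24 and added 41. From 0.5 h to 24 h, then between the untreated groups, 7, 8, 11, 9, 14, 16, 13 and 10 lists were called. Of these calls 0, 3, 5, 4, 5, 8, 2 and 3 held with the estimated correlation, so most were lost with it. Scaling ended 7 and added 6, a pseudocount of 0.1 ended 3 and added 2, the GC and length correction ended 12 and added 9, leaving out 4 libraries ended 27 and added 36, and leaving out 6 ended 21 and added 40. Among lists called with all libraries or without the 4, the direction of the test changed for 11, with these medians without the 4: at 0.5 h other antioxidant enzymes 0.02, homologous recombination −0.03, histones 0.01 and methylation enzymes −0.02; ribosomal proteins 0.07 at 2 h (0.01 and no call with all libraries), 0.25 at 6 h and 0.09 at 8 h; methylation enzymes −0.25 at 4 h; and between the untreated groups other antioxidant enzymes 0.17, histones 0.22 and methylation enzymes −0.29. Counted in the same way, it changed for 10 without 6 libraries, where the 0.5 h values were again 0.02, −0.03, 0.01 and −0.02, ribosomal proteins 0.07, 0.25 and 0.09, and methylation enzymes −0.05 at 2 h, −0.25 at 4 h and −0.06 between the untreated groups. Of the libraries left out, only untreated 0 h replicate 3 is in the comparisons at 0.5 h, 4 h and 6 h. The medians there thus moved because that library left the control. What sets it apart, and the cause of the other changes, was not tested.

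Among the named genes, direction changed for Nqo1 at 6 h with both untreated groups as control (0.05), for Esrrb (−0.14), Hsp90aa1 (−0.16) and Rpl19 (0.27) between the untreated groups without 4 libraries, for Esrrb at 4 h without 6 (−0.11), and for Bard1 (−0.04) and Dppa2 (−0.03) at 24 h with the GC and length correction; the cause was not tested. Calls ended for 317 with only the groups compared, 69 without a filter, 62 with the GC and length correction, 55 with scaling, 36 with both controls, 32 without 6 libraries and 17 without 4. Depth could not be varied, since reads were not used here. On simulated data without shifts of whole libraries, 64% of 1.5-fold changes were recovered, among genes above 5 FPKM.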

Other observations

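The enrichment tests in this part were chosen after the data were seen. At 8 h, 24 of the 251 genes raised at least 2-fold belong to the lysosome, the degradative organelle (276 tested genes, 4.72 times the share among all tested genes, adjusted p = 2.65e-06). Man2b1, a mannosidase, rose from 8.18 ± 1.06 to 23.7 ± 0.935 FPKM (SD, n = 3; log2 change 1.43), and the protease gene Ctsd from 124 ± 14.3 to 260 ± 15.3 (1.07). The glycosidase genes Hexa and Gaa rose by 1.31 and 1.19, the cystine exporter gene Ctns by 1.2, Sidt2 by 1.27, the folliculin gene Flcn by 1.13, the peptidase gene Tpp1 by 1.12 and the membrane protein gene Lamp2 by 1.03. At 10 h, 9 of 131 raised genes belong to the collagen-containing matrix (117 tested genes, 7.99 times, adjusted p = 0.00197), among them Col9a3 (1.61), S100a6 (1.45), Anxa5 (1.13) and Serpine2 (1.07). The median gene lay 0.146 higher at 8 h and 0.127 higher at 10 h than after median-of-ratios scaling. Several of the listed genes lie closer than that to the 2-fold cut, and the enrichment was not repeated on scaled values.

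At 6 h, 9 of the 198 genes lowered at least 2-fold have growth factor activity (49 tested genes, 12.6 times, adjusted p = 0.00012). Gdf3 fell from 74.8 ± 7.23 to 24.7 ± 1.01 FPKM (log2 change −1.56), and Fgf17 changed by −1.84. Lefty2 and Lefty1 were at −1.56 and −1.55, the activin subunit gene Inhbb at −1.53, Bmp4 at −1.24, Tdgf1 at −1.21 and Fgf4 at −1.15. At 24 h 18 of 34 lowered genes belong to the extracellular region (adjusted p = 2.44e-13); most are liver genes, and others are Lefty1 (−1.09) and Trh (−1.08).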
